A study of Mus musculus with 2 samples.

How the data were processed

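Total RNA from the hippocampus of male offspring was pooled within each group, depleted of ribosomal RNA, amplified with random primers, labelled with the dye Cy3 and hybridised to a 1-colour Agilent array, per the labels' protocols. The random priming was meant to label transcripts along their whole length. The scanner images were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, and the array design was built on the mouse genome build mm9, per the file headers. Spot values are Cy3 intensity on a linear scale after background subtraction, per the file headers, with an error estimate and quality flags for each spot. The authors' value table holds 1 log2 value per probe and array. Its processing was inferred from its values, since it is not given in the sources used here. The sorted columns differed by at most 0.08, as after quantile normalization, and each column followed the processed signal of its own array with a Spearman rho of 0.999. The values are therefore direct levels, with medians of 5.85 on both arrays and no centring per gene. The table holds values for 60902 probes, and 96 probes of the scanner data were not used from it.

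Each array has 62939 spots in 384 rows and 164 columns. The 1439 control spots and the array's own negative control probes were left out, which left 60915 probes on 61200 spots. The value of a spot was log2 of the processed signal minus the 75th percentile of that array over these probes. Spots flagged as outliers on either array were removed, which dropped 33 probes altogether, and spots of one probe were averaged on the log2 scale. A probe was measured on an array when it was well above background, in at least 50 percent of its spots where it had several, and 14575 probes were measured on neither array. All differences are glyphosate minus control. With 1 array per group no test was run, and probes were counted by a size rule of 2-fold, or 1 on the log2 scale. For a list of probes, its median was placed among 10000 random lists of the same size matched on mean signal in 20 bins of equal number. These random lists were drawn from all measured probes, since named genes were too few.

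The left side of the grid means columns 1 to 82, the right side columns 83 to 164, the left edge columns 1 to 41, the upper rows 1 to 192 and the lower rows 193 to 384. These areas were set after the data were seen. The comparison of spots of one probe by area kept spots flagged as outliers, since those flags remove the spots that differ. It used the 36 probes with at least 10 spots that were well above background.

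The 15 reference probes carry RefSeq accessions, and all 15 matched a gene symbol in a RefSeq gene table of assembly GRCm38.p6, which was used for names only because the array was designed on mm9. The control probes for Gapdh and Pgk1 were named by their identifiers. No other probe was paired with a gene, and no coordinates are given. For this reason 40 of 41 gene lists, the check of the animals' sex by gene, and named coding genes past 2-fold are not analysed here. The rule for named genes, fixed before the data were examined, took from each list up to 4 measured members with the largest difference. This named Tbp, Gapdh, Tfrc, Ppia, Hsp90ab1 and B2m. The other reference genes and the Pgk1 control probes were added after their values were seen, to give the whole set. The size rule for genes took the largest differences among those measured on both arrays, with a mean signal at or above the 25th percentile and 2-fold in the same direction in all 6 settings. Without gene names it was applied to probes, and 2 were kept per direction.

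The alternatives fixed before the data were examined were quantile normalization, a shift by the median of measured probes, a signal-dependent loess with a span of 0.3, the authors' table, other filters on dim probes, thresholds of 1.5-fold and 4-fold, another flag for detection, and for the gene list a mean in place of a median and random lists not matched on signal. Background correction with normexp on the mean spot signal was planned as well, but that column was not used here. The median spot signal was used for it with an offset of 50, which was chosen after seeing the data, as were the settings limited to one side of the grid the spot precision with outliers kept, the medians of the lincRNA-named probes in all settings and those of the ASMM10UP probes. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

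The size rule was tested on simulated differences with the noise of replicate spots from the whole grid, with 200 changed probes among the 43067. It recovered 7.5% of probes changed by 1.5-fold, 51.0% at 2-fold, 98.5% at 3-fold and 100.0% at 4-fold. Between 154 and 192 of 42867 unchanged probes passed 2-fold. With the noise of spots in the right side, 4 to 14 of 21905 unchanged probes did. These simulations hold spot noise only and leave out variation between samples, labelling and hybridisation. The noise was drawn by brightness alone, from 39 replicated probes, so it leaves out the dependence on position within each area. The counts of unchanged probes therefore do not describe the left edge. A change of 2-fold sits on the threshold itself, so a recovery near 51.0% there follows from the rule. The list step placed 3 of 40 unshifted lists of 100 probes and 40 of 40 such lists shifted by 0.3 outside the central range, and was not tested on a list as short as that of 7 genes. The number of arrays limits the precision. The spread of the between-array difference over spots of one probe was wider for dim probes. It was wider at the left edge than in the right side, by far more for dim than for bright probes.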

Results

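The transcripts of the hippocampus, a brain region needed for forming memories, were profiled in male ICR mouse offspring at postnatal day 28. ICR is an outbred mouse stock. The mothers of the exposed offspring drank water with 0.38% glyphosate (1% Roundup) in pregnancy, equal to 50 mg per kg per day. Glyphosate is the herbicide in Roundup. Mothers of the control offspring drank purified water, and each group had 8 pregnant mice. RNA of each group was pooled and hybridised to 1 array, so the series holds 1 control array and 1 prenatal glyphosate array. The number of offspring in each pool is not given in the sources used here. No difference below has a replicate check, and no test between the groups was possible. The SDs given for genes are over spots of one probe and leave out all variation between animals.

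The arrays had similar reach above background. Of the spots that are not controls, 73.8% were well above background on the control array and 73.3% on the glyphosate array. The median signal was 51.9 on the control array and 66.1 on the glyphosate array, and the 75th percentile was 226 and 305. No spot was saturated. Both arrays lie on one slide and come from one scan, so no scan batch separates them. Differences are glyphosate minus control on the log2 scale after each array was set to its own 75th percentile, and the number of arrays limits their precision.

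Apart from the control probes for Gapdh and Pgk1 given below, the probes with a gene name were those of 15 reference genes with 20 spots each on each array. The series asks how prenatal glyphosate changes the RNA profile of the hippocampus, and these genes give values with an error over replicate spots. None of the 15 differed by 2-fold in either direction. This says little, since only 2.40% of all measured probes did so, and 0.95% of the 10767 brightest. Tbp, which encodes the TATA-binding protein of the transcription machinery, was the highest relative to control, at 0.39 ± 0.05 (SD over 18 spots), or 1.31-fold. Its spots ranged from 0.31 to 0.46. The difference of Tbp lay between 0.36 and 0.43 under the 5 other processing settings. The other 14 genes lay between -0.16 and 0.12.

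Tfrc, which encodes the transferrin receptor for iron uptake, differed by 0.12 ± 0.02 (SD over 20 spots), and Gusb, which encodes the lysosomal beta-glucuronidase, by 0.07 ± 0.07 (SD over 19 spots). Tbp, Tfrc and Gusb were positive under every scaling tried, but the value of Tfrc was 0.03 after quantile normalization and 0.19 after normexp background correction. Gk, which encodes glycerol kinase, was negative under every scaling tried, at -0.05 ± 0.10 (SD over 15 spots), which is within the spread of its spots. The sign of the other 11 genes changed with the scaling, so no direction is given for them. Among these, the glycolytic gene Gapdh had a value of -0.16 ± 0.03 (SD over 16 spots) and 0.00 after quantile normalization. Ppia, which encodes the chaperone cyclophilin A, had -0.08 ± 0.03 (SD over 19 spots) and 0.03 after quantile normalization. The alpha-tubulin gene Tuba1b had -0.11 ± 0.04 (SD over 20 spots) and 0.02 in the authors' table. Ldhal6b, a lactate dehydrogenase relative, had -0.16 ± 0.16 (SD over 15 spots), and -0.08 ± 0.45 over all 20 spots with outliers kept.

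The actin gene Actb (0.07 ± 0.03, SD over 19 spots), Hprt of purine salvage (0.04 ± 0.03, SD over 19 spots) and the nuclear RNA-binding gene Nono (0.07 ± 0.05, SD over 18 spots) were slightly positive and turned negative after quantile normalization. The chaperone gene Hsp90ab1 had -0.02 ± 0.02 (SD over 15 spots), the ribosomal protein gene Rpl13a -0.03 ± 0.02 (SD over 18 spots), and B2m, a subunit of MHC class I, 0.01 ± 0.03 (SD over 19 spots). G6pd2, a glucose-6-phosphate dehydrogenase gene, had -0.01 ± 0.14 (SD over 20 spots).

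**Figure D1:**
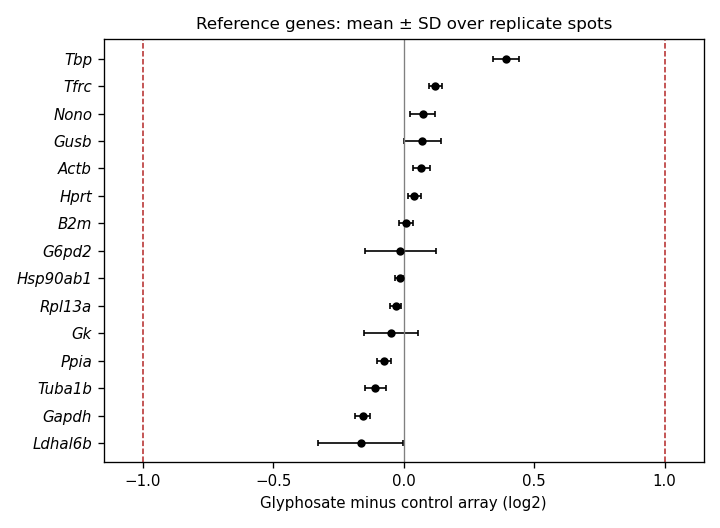
The horizontal axis is the log2 difference between the glyphosate and the control array after 75th percentile scaling, and each row is a reference gene. Points are means and bars SDs over replicate spots, and dashed lines mark a 2-fold difference. Tbp sits at 0.39 and the other 14 genes between -0.16 and 0.12.

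Of the 41 gene lists fixed for this tissue and treatment, only the list of housekeeping genes had at least 5 members that could be named on the array. Of its 7 named members, 5 were positive (Tbp, Tfrc, Gusb, Actb and Hprt) and 2 negative (Ppia and Gapdh), though only Tbp, Tfrc and Gusb kept their sign in every setting. Their median difference was 0.07. This lay at the 68.7th percentile of 10000 random lists of probes matched on mean signal, inside their central range of -0.15 to 0.21. The list kept a place inside the central range in all 8 alternatives, though the median shift among them cannot move a percentile. This says little, since each member averaged 16 to 20 spots, while most probes in the random lists had 1 spot. The noise of single spots widens the central range. For the lists of neurons, glia, synapses, glutamate and GABA receptors, neurotrophins, autism risk genes and known brain noncoding RNAs, no probe could be named, so they are not analysed here.

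Gapdh is also read by a pair of control probes near the ends of its transcript. The probe toward the 3′ end differed by 0.00 ± 0.05 (SD over 10 spots) and the probe toward the 5′ end by 0.16 ± 0.03 (SD over 6 spots), against -0.16 for the reference probe above. The 3 probes of this gene thus disagreed by more than the SD over spots. For Pgk1, another glycolytic gene, the 3′ probe differed by 0.17 ± 0.01 (SD over 10 spots) and the 5′ probe by 0.14 ± 0.08 (SD over 9 spots). These control probes were compared after 75th percentile scaling only.

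Over the whole array, 43067 probes were measured on both arrays. Of these, 434 were at least 2-fold higher and 601 at least 2-fold lower on the glyphosate array, together 1035 or 2.40%. Higher and lower probes were near balance after quantile normalization (492 and 510) and loess (499 and 507), and numbered 137 and 149, together 286, after normexp. A difference of under 1.5-fold was found for 39293 probes (91.2%). At least 4-fold differences numbered 35 higher and 60 lower. The values in the authors' table gave 998 probes with a 2-fold difference, and 915 of these were among the 1035 with the same direction. How often a probe passed this threshold depended on where it lies on the array. The left side of the grid held 48.7% of the measured probes but 70.0% of the higher and 82.2% of the lower ones. In the upper rows of the left edge, 8.14% of the probes were lower and 0.716% higher. In the lower rows of the left edge, 3.29% were higher and 0.50% lower. In the right side, 130 probes (0.588%) were higher and 107 (0.484%) lower, together 237. This side held 147 higher and 82 lower probes after loess, and 62 higher and 30 lower after normexp.

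**Figure D2:**
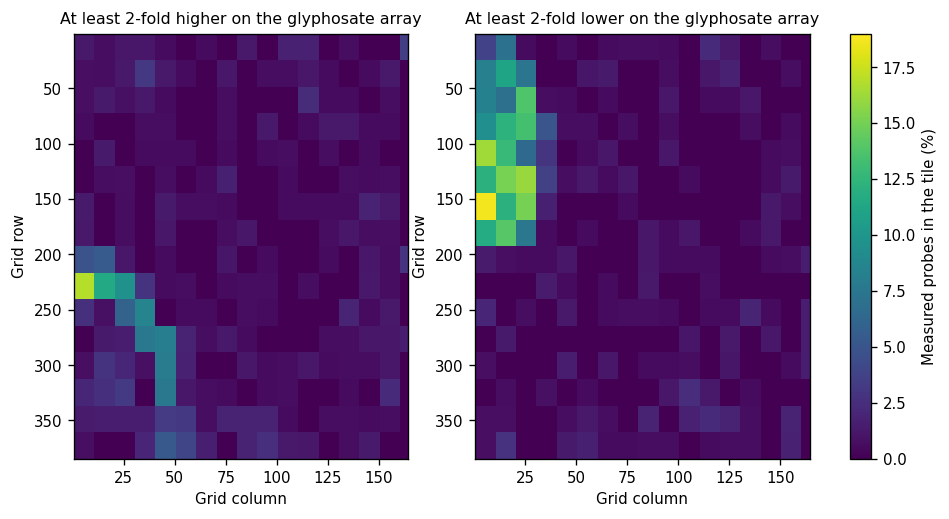
Each panel maps the array by grid column and row in tiles of 24 rows and 10 columns, and colour gives the percent of measured probes in a tile that were at least 2-fold higher (left panel) or lower (right panel) on the glyphosate array. Lower probes gather at the upper left, up to 18.7% of a tile, and higher probes at the lower left, up to 16.9%.

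Spots of one and the same probe showed the same dependence on position. The 9 spots of Gk in the right side averaged 221 ± 10.3 (SD) on the control array and 288 ± 18.6 on the glyphosate array, before scaling. The 3 Gk spots in the upper rows of the left edge averaged 232 ± 11.3 on the control array and 214 ± 69.2 on the glyphosate array. The 2 Gk spots in the lower rows of that edge averaged 98.5 ± 2.11 on the control array and 200 ± 61.6 on the glyphosate array. A spike-in control probe of the ERCC set lost signal in the same places, with 122 ± 6.84 (3 spots) against 217 ± 13.4 (19 spots in the right side) on the glyphosate array in the upper rows, and 89.3 ± 21.8 (5 spots) against 159 ± 12.3 on the control array in the lower rows, where the glyphosate array also had a lower mean of 169 ± 64.7. Over the 20 replicated probes above the 75th percentile, no spot in the left edge lay 0.5 or more from the level of its probe in the right side. The values of the bright reference genes therefore changed little with position, and Tbp differed by 0.39 ± 0.05 (SD over 9 spots) in the right side alone.

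Apart from the reference probes and the control probes for Gapdh and Pgk1, the array's probes have no gene name in the sources used here, so 4 are given by identifier. They were chosen by size among probes that passed 2-fold in the same direction in all 6 settings, which held for 115 higher and 147 lower probes, of which 52 and 30 lie in the right side. Probe ASMM10P036503 had the largest difference, 8.09, with a signal of 17.6 on the control array and 6466 on the glyphosate array. Its scanner errors were 3.26 and 647. Probe ASMM10P031296 was higher by 4.49 (62.0 against 1880 on the glyphosate array). Probe ASMM10P022862 differed by -4.43 (536 against 33.7 on the glyphosate array) and probe ASMM10P043062 by -4.31 (646 against 44.1). After normexp the differences of these 4 probes were smaller, at 6.0, 3.66, -3.01 and -3.13 in the same order. Each of the 4 has 1 spot per array, and only ASMM10P043062 lies in the right side.

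**Figure D3:**
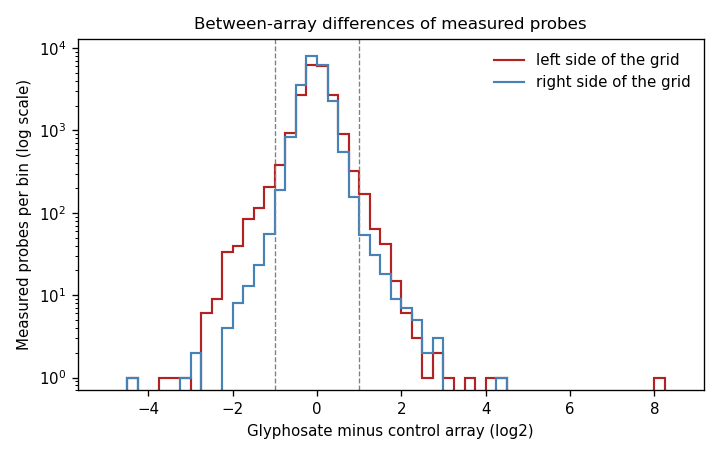
The horizontal axis is the log2 difference between the glyphosate and the control array in bins, and the vertical axis is the number of measured probes per bin on a log scale. Lines give the left and right sides of the grid, and dashed lines mark a 2-fold difference. The left side holds 798 probes past 2-fold and the right side 237, and the single probe beyond 8 lies in the left side.

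The probes whose identifiers contain lincRNA, the usual short name for long intergenic noncoding RNA, were the only ones that could be taken as noncoding by name. At 329 mouse loci both a plus and a minus probe are present, and which one reads the named transcript is not given here. The array is described as profiling long noncoding RNAs, so an unknown share of the other probes may be noncoding too. The comparison below is therefore not one of noncoding with coding probes. Of 1835 such probes, 735 were measured on both arrays, and 9 were at least 2-fold higher and 21 at least 2-fold lower on the glyphosate array. After normexp these were 2 and 3. Without it, probes named human lincRNA made up 7 of the 9 higher and 14 of the 21 lower, though the RNA is from mouse. In the right side, 0 of 402 lincRNA-named probes were higher and 3 were lower. As groups they lay slightly below other probes of the same brightness. The 303 measured probes named mouse lincRNA had a median difference of -0.17 where matched random lists had a median of -0.08, and the 432 named human lincRNA had -0.17 where matched lists had -0.08. For both groups, none of 10000 matched random lists had so low a median. In the right side the medians were -0.17 and -0.20, at the 0.39th and 0th percentile. Under the 5 other processing settings the medians lay between -0.23 and -0.10 and at the 0th percentile each time. These settings are not all separate checks. The median shift cannot move a percentile, and the authors' table is close to quantile normalization. The gap of both groups to the matched lists was 0.09, and 0.05 after normexp. Few probes of the E1A, ERCC, ETG and DCP control sets were well above background on both arrays. These were 1 of 10 E1A, 4 of 12 ERCC, 4 of 13 ETG and 3 of 18 DCP probes. The 12 were mostly negative too and lay between -0.52 and 0.14, without matching on brightness. The 10767 dimmest measured probes had a median of -0.12 as well, so a negative value was common among dim probes. Without matching, the control probes cannot show whether the gap to matched lists occurs outside the lincRNA-named probes. The cause of this gap was not tested. The 390 measured probes of another identifier class, ASMM10UP, had a median of -0.02, at the 99.3rd percentile of matched lists, but -0.08 and the 53.8th percentile in the right side.

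Another 3240 probes were well above background on 1 array only, 1776 on the control array and 1464 on the glyphosate array. For these only a bound can be given, the brighter array against the higher of the dim spot's own signal and the lowest signal well above background on that array. This bound reached 2-fold for 276 probes seen on the control array and 141 seen on the glyphosate array. In the right side it did so for 46 and 26. The largest bounds were at least 25.5-fold for a probe higher on the control array and at least 20.2-fold for one higher on the glyphosate array.

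Across the 43067 probes, which are not independent replicates, the arrays had a Pearson r of 0.990. The median SD of a between-array difference over the spots of a reference gene was 0.03, with a range over the 15 genes of 0.02 to 0.16. With spots flagged as outliers kept, the SD was 0.37 for Gk and 0.45 for Ldhal6b. Most reference genes were brighter than most measured probes. For replicated probes below the 75th percentile, outliers kept, each spot difference was taken relative to the median of its probe in the right side. The SD of these deviations, pooled over probes, was 0.25 in the right side. It was 0.65 in the upper rows and 0.60 in the lower rows of the left edge. The differences of all measured probes had an SD of 0.38. It was 0.44 among the 10767 dimmest of these probes and 0.27 among the 10767 brightest.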

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

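The settings limited to one side of the grid, the normexp correction, the spot precision with outliers kept and the lincRNA medians in all settings were chosen after seeing the data. The 1035 probes past 2-fold numbered 998 to 1022 under quantile normalization, median shift, loess and the authors' table. The higher and lower counts moved from 434 and 601 to 499 and 507 under loess. The count was 286 after normexp, which changed the signal column, the background correction and the offset together. It was 4337 with no background filter, 309 above the median signal and 237 in the right side of the grid. It was 3774 at 1.5-fold and 95 at 4-fold. The 30 lincRNA-named probes became 5 after normexp, 237 with no filter, 5 above the median signal, 3 in the right side, 75 at 1.5-fold and 2 at 4-fold. The 3240 probes seen on 1 array numbered 1323 in the right side and 1917 in the left. Smaller areas and other thresholds hold other numbers of probes by construction. For the rest the cause was not tested. No reference gene reached 2-fold in any setting, nor did the gene list leave its central range. The spot precision lay between 0.03 and 0.04 and the Pearson r between 0.987 and 0.993. Of 129 recomputed values for named genes, probes and lists, 60 moved by more than their spread. No probe given by identifier changed direction, which the rule that chose them required, so this is no separate check. The filter at the median signal left 14 of the 15 reference genes. Not run were normexp on the mean signal and the choice of 1 probe per gene, since each named gene had 1 reference probe. No paired analysis was possible because each group has 1 array.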

Other observations

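The tests of the scaling for Tbp and of the neighbouring spots were set before their results were seen, and the other tests below were chosen after.

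Loci on the array with a pair of lincRNA-named probes, one marked plus and the other minus, allow a look within loci. Of 329 such pairs in the mouse lincRNA set, 54 had both probes measured on both arrays, 160 had 1 probe measured and 115 had neither. Across the 54 pairs, which are not independent replicates, the differences of the plus and minus probes had a Pearson r of -0.04 and a Spearman rho of -0.02. Both probes had the same sign in 37 pairs, where unrelated signs would give 34.7, since most of these probes were negative.

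Probes past 2-fold lay mostly in the left side of the array, with a share 3.55 times that of the right side, and 2.22 times after normexp. Probe brightness does not account for it, since the ratio was 3.58 with the left side weighted to the signals of the right. Position on the array surface may account for it. Among 16 dim probes with replicate spots, each spot difference was taken relative to the median of its probe in the right side. Pooled over probes and rows, the SD of these deviations was 2.95 times as large in the left edge as in the right side. It was at least 2.58 times as large with any 1 probe left out. In the upper rows of the left edge, dim replicated spots deviated by a mean of 0.08 on the control and -0.30 on the glyphosate array. In the lower rows they deviated by -0.96 and -0.56. These shifts have the directions of the probes past 2-fold there. A transcript level is the same for all spots of a probe, so the shifts argue against it for these replicated probes. For probes with 1 spot, transcript levels that differ between the pools were not tested as a part of this excess. The ratio of 3.55 is the pattern itself and no second pair of pools was compared. The 237 probes past 2-fold in the right side, 92 after normexp, stay open too.

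Tbp stood apart from the other 14 reference genes, though a difference of its size was not exceptional among all measured probes. A local defect of the array would leave some of its spots within the range of the other genes, but the lowest of all its 20 spots, outliers kept, lay at 0.31, above the highest other mean of 0.12. The scaling does not account for it, since the smallest gap between Tbp and the next gene was 0.17 over all 6 settings, after normexp. The median shift among these cannot change the gap. A higher Tbp level in the pool from exposed offspring cannot be told apart from a property of this probe or pool, because Tbp has 1 probe and each group 1 pool. The 3 probes of Gapdh lay between -0.16 and 0.16. The 12 probes of the E1A, ERCC, ETG and DCP control sets that were well above background on both arrays lay between -0.52 and 0.14. Differences of the size of Tbp's thus occurred among them in the negative direction. The only E1A spike-in probe of 10 that was well above background, for example, had -0.44 ± 0.17 (SD over 35 spots). These control probes were dimmer than Tbp, with mean signals of 15.9 to 147 on the control array against 290. Their SDs over spots were 0.17 to 0.86, so they are no like measure for Tbp. The differences of all 43067 measured probes had an SD of 0.38, and those of the 10767 brightest an SD of 0.27. A difference of the size of Tbp's thus lies within the ordinary spread of the array. Most of these probes had 1 spot, so spot noise adds more to their spread than to the mean of Tbp.

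Probe ASMM10P036503, at 8.09, lies in the lower rows of the left edge, where dim replicated probes lost signal on both arrays, by a mean deviation of -0.96 on the control array and -0.56 on the glyphosate array. The largest deviation among 643 spots of replicated probes was 2.67, so no loss seen in these spots reached this difference. These spots belong to 36 probes, while ASMM10P036503 was the largest of 43067, so a rarer effect of position cannot be excluded. A bright mark on the glyphosate array would raise its neighbours, but of 31 measured spots within 2 rows and 4 columns, 2 (6.45%) were at least 2-fold higher. A defect of this single spot and a transcript present mainly in the exposed pool both stay open, since the probe has 1 spot per array and no gene name here.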
